A study of Mus musculus with 2 samples.

How the data were processed

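Expression was measured in total RNA from the sorted leukaemic cells on 1 Agilent 1-colour (Cy3) mouse array per group. The groups were taken from the source names in the labels. The deposited scanner files hold spot intensity values on a linear scale, background-subtracted and detrended within each array, per the file headers. The headers name Agilent Feature Extraction 11.0.1.1, while the submitters' processing notes name version 9.1. The deposited value table holds log2 values by the authors. Its columns share their quantiles, with a median of 5.90 in both, and correlated with log2 of the processed signal of their own arrays with r = 0.995 for SoNar-high and r = 0.994 for SoNar-low. Shared quantiles are what quantile normalization gives, but further steps behind the table are not given in the sources used here. It was used only as an alternative. The array annotation in the headers is of the mm9 build, while the table used for gene names is of GRCm38.p6, so no coordinates are given.

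The main values were log2 of the processed signal minus each array's 75th percentile over non-control spots. This setting was fixed before the data were examined. Fewer than 50% of the SoNar-low spots turned out to be well above background (44.8%, against 72.9% on the SoNar-high array), and a percentile over spots detected on both arrays was therefore added as an alternative. Control spots were left out, and 685 spots that the software marked as non-uniform or as population outliers on either array were removed. Spots of a probe were averaged, and a probe counted as detected where most of its spots were well above background. Probes were named through their RefSeq accession without version. Of 39429 probes 27234 were named and 12195 were not. A gene's value was the mean over its probes detected on both arrays, which gave 10517 genes. Probes of a gene disagreed to the point of a 2-fold difference in opposite directions in 5 genes. The difference was SoNar-high minus SoNar-low, and a gene counted as higher or lower at an absolute log2 difference of at least 1. No p-value or standard error was computed, since each group had 1 array.

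A gene with no probe detected on an array has only a bound there. The bound set the normalized level on the detecting array against the higher of the other array's lowest detected level and the probe's own level. The lowest detected processed signal was 19.7 on the SoNar-high array and 46.4 on the SoNar-low array.

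The text names the 12 highest and 12 lowest genes with descriptive names and the same sign under quantile normalization and normexp, up to 2 highest and 2 lowest members of each list described, up to 4 genes per direction with the largest bounds, and a fixed set of metabolic and leukaemia genes, of which 1 is not reported here. This rule and the 41 gene lists, 31 of pathways and 10 of other cell types, were fixed before the data were examined. Each list with at least 3 measured genes was given a median, set among the medians of 10000 random lists of the same size matched on mean level in 10 bins. The megakaryocyte list, with 1 measured gene, and the basophil and mast cell list, with 0, got no value. A list was called apart outside the middle 95% of random lists. Leaving out a member used 2000 random lists.

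The scripts were tested on simulated data. The noise was the median SD between spots of a probe over all repeated probes, dim ones included. With it, 97.0% of genes simulated with a log2 difference of 1.5 and 100% of those at 2 were called. There were 3 calls among the unchanged of 10517 genes. Of 1000 random lists of 20 genes 4.8% were called apart, and 47 of 50 lists shifted by 0.5 were found. Spot noise is smaller than the difference between probes of a gene, so the simulation leaves that error out.

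The alternatives were median scaling, quantile normalization, cyclic loess, normexp background correction with an offset of 50, 3 other filters on dim probes, the brightest probe of a gene, the authors' value table, outlier spots kept, and random lists not matched on level. Normexp used the median spot signal in place of the mean, together with the median local background. After seeing the data 3 more were added: the percentile named above, 1 common limit for both arrays, and centring on the median of measured genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1 were used.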

Results

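The study compared the gene expression of mouse B-cell acute lymphoblastic leukaemia (B-ALL) cells that were sorted from bone marrow by their SoNar signal. SoNar is a genetically encoded fluorescent sensor whose excitation ratio follows the NADH to NAD+ ratio of the cytosol, so cells with a high and a low ratio form the groups SoNar-high and SoNar-low. The comparison asks how leukaemic cells in different metabolic states differ in expression. Each group had 1 array, from mice of 8 weeks, with total RNA labelled with Cy3 and hybridised to a 1-colour Agilent mouse array. The sample titles read N-myc-high for the SoNar-high sample and N-myc-low for the SoNar-low sample. The labels do not explain this other grouping. Of 43020 non-control spots, 31352 were well above background on the SoNar-high array and 19291 on the SoNar-low array, and no spot was saturated. With 1 array per group the differences have no replicate check, no test was made, and the number of arrays limits the precision. The arrays were also scanned in different sessions, so scan batch and group cannot be told apart.

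Over the genes measured on both arrays, the levels of the SoNar-high and SoNar-low arrays correlated with Pearson r = 0.97, with no replicate arrays to set this against. The genes of glycolysis and of mitochondrial respiration did not stand apart from other genes. Of 10517 genes, 512 were at least 2-fold higher and 177 at least 2-fold lower on the SoNar-high array in the main scaling. With median scaling the counts were 139 and 3306. Ldha, the lactate dehydrogenase subunit that couples pyruvate to NADH, had a log2 difference (SoNar-high minus SoNar-low) of 0.23, and Slc2a1, a glucose transporter, one of -0.79. The 6 lists that did stand apart, all on the higher side, were neutrophil genes, with a median log2 difference of 0.48 over 13 genes, erythroid, natural killer and stromal genes, with 3 to 6 measured genes each, and, by smaller margins, cytosolic ribosomal protein genes and MYC target genes of ribosome biogenesis. The median log2 difference of all measured genes was -0.17, and list medians are given beside those of random gene lists matched on level.

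The highest log2 differences among genes with descriptive names were those of Iqcg (3.11), Akap8 (3.07), Gprc5d (3.03), Ap1g2 (2.94), Nkd2 (2.86) and Nanog (2.83). Akap8 anchors protein kinase A in the nucleus, Nkd2 restrains Wnt signalling and Nanog is a transcription factor of pluripotent cells. Next came Cyp46a1 (2.81), the brain enzyme that hydroxylates cholesterol, Npm3 (2.77), a nucleolar histone chaperone, Tra2b (2.76), a splicing regulator, Timm29 (2.75), a part of the mitochondrial import machinery, Cyp2d11 (2.62) and Kpna4 (2.59), an importin. The lowest log2 differences were those of Ly6h (-3.54), Rtn1 (-2.87), Faim2 (-2.70), Denn2b (-2.61), Rab6b (-2.47) and Car14 (-2.30). Vstm2l (-2.24), Fbxl16 (-2.14), the neuropeptide gene Cck (-2.13), Xkr8 (-2.12), a phospholipid scramblase, Cpe (-2.09), which processes prohormones, and Trnp1 (-2.08) followed. Ly6h, Rtn1, Faim2, Cck and Cpe are best known from the nervous system. Each of these 24 values rests on the 1 probe of its gene that was detected on both arrays. Ly6h, Gprc5d, Nkd2, Cpe and Trnp1 also have probes that were left out. For Cpe the signal averaged over all probes was 38.75 on the SoNar-high array and 58.62 on the SoNar-low array. That gap is smaller than the 4.26-fold of its used probe, and the gap of Trnp1 shrank likewise. The left-out probes were not compared on their own. On the SoNar-high array the 12 lowest genes lay under the SoNar-low array's lowest detected level. None of these 12 could therefore be measured with 1 common limit for both arrays.

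A value from 1 probe is weak evidence for its gene here. Among the 2021 genes with exactly 2 measured probes, the log2 differences of the probes correlated across genes with Pearson r = 0.09, against -0.04 to 0.04 for the middle 95% of 1000 shuffled pairings, while their levels correlated with r = 0.44 on the SoNar-high array and 0.40 on the SoNar-low array. Of the 512 higher genes 474 rested on 1 probe, as did 171 of the 177 lower genes. Where several probes measured a gene, 38 genes were at least 2-fold higher on average and 8 of these in every probe, and 6 were at least 2-fold lower on average and 3 of these in every probe. Repeat spots of 1 probe were much closer, with a median SD of 0.15 for the log2 difference over 193 probes.

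In glycolysis all 24 genes were measured, 0 were at least 2-fold higher and 1 was at least 2-fold lower, Aldoc at -1.73. Aldolase C is the aldolase best known from brain. Other extremes were Eno2 (-0.85), Slc16a1 (0.60) and Slc16a3 (0.80), the last 2 being monocarboxylate transporters that carry lactate. Hk2, the inducible hexokinase, had a difference of -0.39. The list median of -0.20 lay at percentile 41.6 of the random lists, whose median was -0.18. For pyruvate entry into mitochondria the median of 12 genes was -0.21, at percentile 36.7. Pdha1, a subunit of pyruvate dehydrogenase, was at 0.13 and its inhibitory kinase Pdk1 at -0.52. Pdp1 (-0.66) and Dld (-0.60) were the lowest members. The pyruvate carrier subunits differed in sign, with Mpc1 at -0.43 and Mpc2 at 0.76. Among the genes measured on both arrays, none of the tricarboxylic acid cycle, the respiratory complexes or ATP synthase reached a 2-fold difference. Cox17 and Cox10, which serve the assembly of complex IV, were among 5454 genes detected on the SoNar-high array alone. In the main scaling they were at least 5.55-fold and at least 3.04-fold higher there. The 18 cycle genes had a median of -0.43 at percentile 16.6, with Sucla2 at -0.85 and the pyruvate carboxylase gene Pcx at 0.29, and stood apart on the lower side only against random lists not matched on level. Complex I (36 genes) had a median of -0.35 at percentile 34.0, complexes III and IV (24 genes) one of -0.22 at percentile 70.0, and ATP synthase (15 genes) one of -0.23 at percentile 78.9. The cytosolic NADH shuttles and NAD synthesis, with Got1 at -0.98 and Got2 at 0.25, had a median of -0.39 at percentile 12.3. This list stood apart on the lower side in 3 alternatives, namely quantile normalization, cyclic loess and the authors' value table. With median scaling every log2 difference is lower by the same amount and the values of Ldha and Pdha1 fall below 0.

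**Figure D1:**
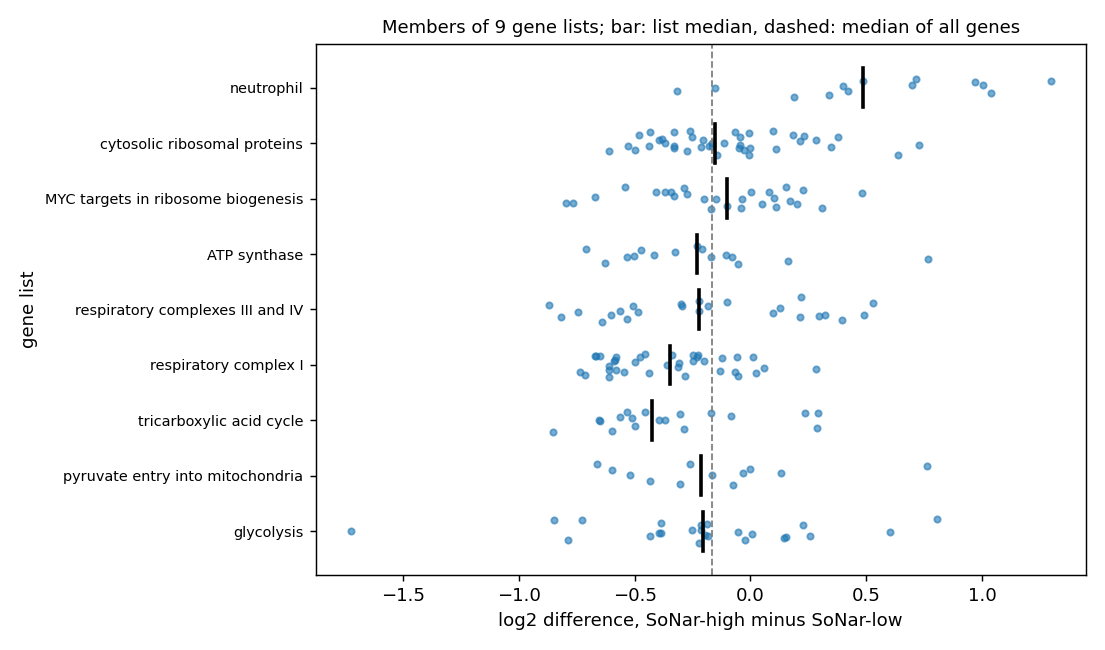
Log2 differences (SoNar-high minus SoNar-low, 1 array per group) of the measured genes of 9 gene lists. Each point is a gene, the black bar is the list median and the dashed line is the median of all 10517 measured genes, -0.17. The neutrophil median of 0.48 lies farthest to the right of that line, and those of glycolysis (-0.20) and complex I (-0.35) lie to its left.

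Cytosolic ribosomal protein genes had a median of -0.15 over 40 genes, against -0.33 for random lists matched in the level bins, which is percentile 99.3. The highest bin spans mean levels from 3.57 to 8.08, so the matching is coarse among bright genes such as these. Rpl4 (0.73) and Rpl7 (0.63) were the highest members and Rplp1 (-0.61) and Rpl37 (-0.53) the lowest. MYC targets in ribosome biogenesis had a median of -0.10 over 27 genes against -0.30, percentile 98.1, with the spermidine synthase gene Srm at 0.48 and Nop2 at -0.80. No member of either list reached a 2-fold difference. Against random lists not matched on level, neither list stood apart. The ribosomal protein call was also lost with cyclic loess, and the MYC target call with quantile normalization, cyclic loess, the stricter filter, the brightest probe and the authors' value table. Leaving out any 1 of 13 MYC targets also took that list inside the middle 95% of random lists, to percentile 96.1 at the lowest.

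The leukaemia and cell cycle genes did not stand apart as lists. Pro-B and pre-B cell genes had a median of -0.18 over 25 genes at percentile 53.7, with Ikzf3, a lymphoid transcription factor, at 1.39 and Ebf1, a factor of early B cell commitment, at -0.92. Later B cell genes had a median of -0.17 over 21 genes at percentile 41.2, with Cd22 at 1.16 and Ms4a1 at -0.83. The probes of Mycn, Igll1 and Il7r were not well above background on either array, and that of Myc was so on the SoNar-high array alone. At -4.39 there, Myc lay under the SoNar-low array's lowest detected level of -3.36, so this gives no evidence that Myc differed. The genes of the G1 to S step had a median of -0.17 over 26 genes at percentile 91.0, with the replication licensing gene Cdc6 at 1.41. Those of G2 and mitosis had a median of -0.29 (25 genes, percentile 58.2), with Aurkb, a mitotic kinase, at 2.45 and Plk1 at -0.80. The proliferation marker Mki67 had a difference of 0.01. Creb1, a transcription factor of the cAMP response, had one of -0.56, from the 1 of its 2 probes that was detected on both arrays. The other Creb1 probe was detected on the SoNar-high array alone and was left out. The cAMP and immediate early genes had a median of -0.19 over 22 genes at percentile 38.8, with Ppargc1a at -1.54.

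Markers of several other cell types were higher on the SoNar-high array relative to genes of like level. Median scaling lowers every log2 difference by 0.61, which takes the neutrophil and stromal medians below 0 but leaves each list's margin over random lists unchanged. The values that follow are those of the main setting. Of 13 measured neutrophil genes, 12 lay above the median of all genes and 3 were at least 2-fold higher, and their median of 0.48 was at percentile 99.97, against -0.18 for random lists. Ngp (1.29) and Retnlg (1.04) were the highest and S100a9 (-0.15) and Prtn3 (-0.32) the lowest. Erythroid genes had a median of 0.88 over only 4 genes, with Hba-a1, an alpha globin gene, at 1.88, Tfrc at 0.10 and Hemgn at -0.83, and natural killer cell genes one of 1.12 over only 3 genes, with Prf1, the perforin gene, at 1.21. Stromal and endothelial genes had a median of 0.54 over 6 genes, with Kdr at 1.54 and Alpl at -0.83. These lists lay at percentiles 99.7, 99.3 and 98.6. Without Ermap the erythroid list fell to percentile 80.5 and without Hba-a1 to 82.9, and the stromal list fell to 93.8 without Kdr, so both depend on single genes. The erythroid call was also lost with detection on at least 1 array, and the natural killer and stromal calls with that setting and with no filter on dim probes. T cell genes (median 0.03, percentile 70.2) and dendritic cell genes (-0.16, percentile 62.1) lay inside the middle 95% of random lists. Of 39 lists with a value, 6 stood apart on the higher side and 0 on the lower in the main setting, where chance gives 1.95 in all. Lower calls appeared for 3 lists with quantile normalization (the NADH shuttles, the cell cycle inhibitors and the interferon response), for 2 with cyclic loess and for 3 in the authors' value table. Detection on at least 1 array gave 1 lower call (the cell cycle inhibitors), and random lists not matched on level gave 1 (the tricarboxylic acid cycle). These percentiles describe the 2 arrays and not the conditions.

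**Figure D2:**
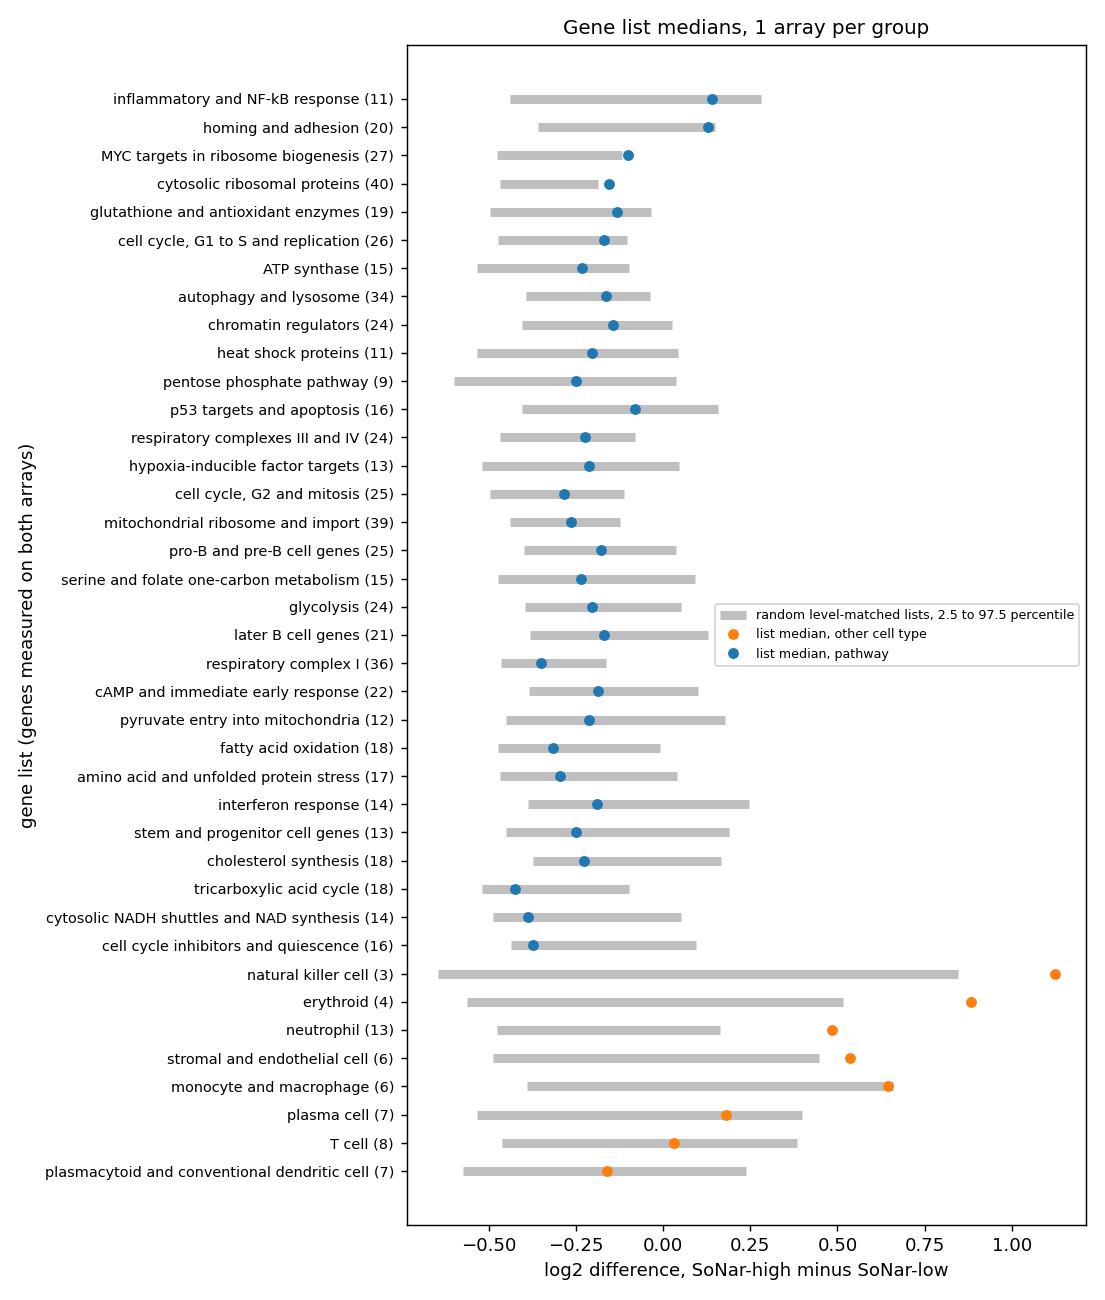
Median log2 difference (SoNar-high minus SoNar-low, 1 array per group) of each of 39 gene lists, with the number of measured genes in brackets. Grey bars span the middle 95% of the medians of 10000 random lists of the same size and level. The dots of 6 lists lie to the right of their bars, the neutrophil list (0.48) among them, and 0 lie to the left.

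Many genes were detected on the SoNar-high array alone. These were 5454 genes, against 11 detected on the SoNar-low array alone, out of 20618. The bound reached 2-fold for 366 of the 5454 and for all 11. For such genes only a bound can be given, and it holds for the main scaling. With median scaling every bound on the SoNar-high side is lower by 0.61 on the log2 scale. On the SoNar-high side Scgb1a1, a secretory protein of the airway, was at least 10.3-fold higher, Lyz1, a lysozyme gene, at least 9.96-fold, Zfp982 at least 7.84-fold and Fsd1l at least 7.67-fold. On the SoNar-low side Tceal3 was at least 9.42-fold higher, Syt1, a calcium sensor of synaptic vesicles, at least 6.71-fold, Atp8b1 at least 6.20-fold and the olfactory receptor gene Olfr611 at least 5.44-fold. Detection on the SoNar-high array extended to families not expected in marrow: 44.1% of 1159 olfactory receptor probes were well above background there, against 5.52% on the SoNar-low array.

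The counts of higher and lower genes depend on the scaling. Of the genes with a 2-fold difference, 74.3% were higher on the SoNar-high array in the main setting, 4.03% with median scaling, 52.4% with quantile normalization, 45.4% in the authors' value table and 92.3% with the 75th percentile taken over spots detected on both arrays. Median scaling lowered all log2 differences together, giving a change of -0.61 in the median, and the last of these settings raised them by 0.21.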

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

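The items here lie outside the main comparison. The control spots for the E1A spike-in are not used in any comparison of genes. Their median background-subtracted signal was 17.8 on the SoNar-high array, above the upper end of the middle 95% of that array's negative control spots, 3.08. On the SoNar-low array the same 320 spots had a median of 0.27. Probes without a gene name here also differed: 600 were at least 2-fold higher and 52 at least 2-fold lower on the SoNar-high array, of 3833 measured on both.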

How the results depend on the processing

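No paired analysis was possible because each group had 1 array, and for the same reason no array could be left out. The 3 settings added after the data were seen are the percentile over spots detected on both arrays, the common limit and the centring on the median. Against 512 genes at least 2-fold higher in SoNar-high, the count was 139 with median scaling, 262 with normexp, 2775 with no filter, 3203 with detection on at least 1 array and 806 with the percentile over spots detected on both arrays, and it stayed within 1.5 times under the other 8 settings. Against 177 lower genes, it was 3306 with median scaling, 350 with quantile normalization, 60 with normexp, 1751 with no filter, 96 with the stricter filter, 430 in the authors' value table, 67 with the percentile over spots detected on both arrays, 114 with the common limit and 70 after centring. Shifting all values or keeping dimmer probes gives such changes by construction, and for normexp, quantile normalization and the authors' table the cause was not tested. Genes detected only on the SoNar-high array fell from 5454 to 2800, and only on the SoNar-low array from 11 to 4, when a signal over 2 times the detection level was demanded. Median scaling, the percentile over spots detected on both arrays and the centring shift all genes alike and cannot change a list's margin, which leaves 11 alternatives that can. The neutrophil list stood apart on the higher side in all 11, its margin over random lists going from 0.67 to 0.84 with the stricter filter. The margin of the MYC target list, 0.20, ended its call at 0.11 with quantile normalization, 0.12 with cyclic loess, 0.18 with the stricter filter, 0.15 with the brightest probe, 0.12 in the authors' table and 0.067 without matching on level. That of the ribosomal proteins, 0.18, did so at 0.13 with cyclic loess and 0.012 without matching. The erythroid margin of 1.01 was 0.82 with normexp, 0.49 with no filter and 0.45 (call lost) with detection on at least 1 array. The natural killer margin of 1.14 was 0.73, 0.12 and 0.45, with the call lost in the last 2, and under the stricter filter too few of its genes were left for a value. The stromal margin of 0.62 was 0.46, 0.43 and 0.45, with the call lost in the last 2, and 0.84 with the stricter filter. For these lists the cause was not tested. Glycolysis stayed inside the middle 95% of random lists in all 11. Of lists not apart in the main setting, the monocyte list was higher in 7 and homing in 2, and the NADH shuttles, cell cycle inhibitors and interferon response were lower in 3 each and the tricarboxylic acid cycle in 1. The naming rule, applied to all lists, covers 53 genes with a 2-fold difference, some of them not named in the text. Of these 0 changed sign, but the naming rule and the size of the shifts fix much of this. Signal over background limits the dim genes, most of all on the SoNar-low array.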

Other observations

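All tests here were chosen after the data were seen. Only for the common limit and the array surface were the bounds set before the test was run. After a first value was seen, the tests on the olfactory receptors and on T cell and dendritic cell genes were given stricter bounds, and the test on brain genes was replaced by another statistic.

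Some gene groups not described above lay within the middle 95% of random lists in the main setting. Homing and adhesion genes had a median of 0.13 over 20 genes at percentile 96.7, with the integrin genes Itgb2 at 1.15 and Itga6 at -0.80 and the chemokine receptor gene Ccr9 at -0.89, and stood apart on the higher side in 2 of 11 alternatives that can change a list's margin. Glutathione and antioxidant genes had a median of -0.13 over 19 genes at percentile 89.3, with Cat, the catalase gene, at 1.25 and Hmox1 at 1.17. Cell cycle inhibitors and quiescence genes had a median of -0.37 over 16 genes at percentile 7.94, with Cdkn2d at -0.94, and stood apart on the lower side in 3 of 11 alternatives (quantile normalization, detection on at least 1 array and the authors' value table). Monocyte and macrophage genes had a median of 0.64 over 6 genes at percentile 97.2, with Csf1r at 1.25, and stood apart on the higher side in 7 of the 11. Plasma cell genes had a median of 0.18 over 7 genes at percentile 88.6, with Prdm1 at 1.48.

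More probes were well above background on the SoNar-high array. A defect gathered in a small part of the array surface is argued against. A common limit was set at the SoNar-low array's lowest detected level. Of the spots above it detected on the SoNar-high array alone, the richest 10% of array tiles held a share of 0.168. That is under the bound of 0.2 set before the test, and of all spots detected on the SoNar-high array alone the share was 0.129. The test cannot speak to a diffuse or graded defect. The software marked 350 spots as non-uniform on the SoNar-high array and 1 on the SoNar-low array, and these were removed. With the common limit the SoNar-high array had 1.149 times as many probes above it, 20648 against 17977. The ratio was 0.99 with median scaling and 1.21 with the percentile over spots detected on both arrays, values added afterwards. Each array's own limit gave 31352 against 19291 spots, so most of the gap lay under the common limit. A higher detection limit of the SoNar-low array may account for that part, while the rest changed with the scaling and remains open. Olfactory and vomeronasal receptor probes lay above the common limit 2.01 times as often on the SoNar-high array. This met the first bound of over 2 times, and a condition on the scaling was added afterwards. The figure was 1.13 times with median scaling and 2.39 times with the percentile over spots detected on both arrays. For these probes a broad rise of signal at genes not expected in marrow cannot be told apart from the choice of scaling. Without scaling, the E1A control spots had medians of 17.8 on the SoNar-high array and 0.27 on the SoNar-low array. The negative control spots had -5.90 and -6.53, so the control spots leave the question open. A wider expression in SoNar-high cells was not tested.

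Neutrophil genes were higher on the SoNar-high array relative to genes of like level. A rise of dim signal is argued against, since the 8 neutrophil genes brighter than the 75th percentile on the SoNar-low array had a median of 0.45 at percentile 99.96. A lower share of leukaemic cells would raise the markers of other types alike, and the neutrophil median exceeded that of 15 T cell and dendritic cell genes by 0.59, with a 95% bootstrap interval over genes of -0.20 to 1.24, which leaves it open. These 2 lists had been seen not to stand apart, while the monocyte (0.64), erythroid (0.88), natural killer (1.12) and stromal (0.54) medians, over 3 to 6 genes each, were at least as high as the neutrophil one. More neutrophils or their precursors in the SoNar-high sort, or expression of these genes in the leukaemic cells, may also account for it. A gate on the sensor could remove cells that do not carry it, but the labels do not describe the gates.

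Of the 12 lowest genes named, at least 5 are best known from the nervous system, and the rest of the 12 were not sorted by tissue. Cyp46a1, among the highest, is a brain gene too, and no enrichment was tested. Brain RNA on the SoNar-low array was therefore weighed only as a hypothesis that may account for the lowest genes. Of a list of 54 abundant brain genes, 12 had first been seen among the lowest and were left out. Of the other 42, the 24 measured on both arrays had a median of -0.29 against -0.14 for random lists, percentile 9.87. Of these, 4 were at least 2-fold lower and 1, Snap25, at least 2-fold higher on the SoNar-high array. Keeping the 12 would count the genes that raised the question. Leaving them out removes genes that brain RNA predicts to be low and moves the percentile inward, so it decides nothing. Of the 19 whose brightest probes lay under the common limit on the SoNar-high array, 5 were well above background on the SoNar-low array, Syt1 and Syn1 among them, a share of 0.263 (95% exact binomial interval 0.091 to 0.51), against 1.49% of all such probes, and without Syt1, named above for its bound, 4 of 18. Slc1a2, Nefl, Gap43 and Ckb, all abundant in brain, were among the 14 that were not. Of the 5, Pcp4, Syn1, Eno2 and Scg3 were well above background on the SoNar-high array too, and Syt1 was not. Eno2 (-3.36) and Syn1 (-3.37) lay just under the limit there. In the other direction, Ckb, Slc17a7, Cplx1, Vsnl1, Ndrg2, Gfap and Syn2 were detected on the SoNar-high array alone, as were many other genes. The first form of the test, the median over the brightest probes of 41 genes, was -0.32 (95% bootstrap interval -0.74 to -0.07), above the -1 it asked for, but it held genes near background and genes bright on both arrays, so brain RNA stays open, as does expression by the leukaemic cells, which was not tested.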
